A study of Mus musculus with 14 samples.

How the data were processed

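RNA sequencing of 14 libraries was examined from 2 processed tables, and no reads were re-aligned. The libraries came from total RNA of snap-frozen lung tumor nodules of C57BL/6 mice with a HER2 exon 20 YVMA allele. The labels put 2 libraries in the vehicle group and 3 each in the mobocertinib, T-DM1, combination and resistant groups, the last from nodules with acquired resistance to mobocertinib alone. Replicate numbers follow the accession order and only name a library. The labels do not state that each library came from a separate animal, although titles hold animal-like numbers, so p-values measure only the spread between these samples.

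The authors' first table gives whole-number counts for 55291 gene symbols, of which 24822 had a count of 0 in all libraries. The deposited second table gives TPM values for 47606 genes, adjusted by the authors for transcript length and library size, on another gene annotation. Per the submitters' processing notes, STAR, RSEM and the mm10 build were used. Their roles and versions, the annotation and the strand setting are not given in the sources used here. All 14 columns of each table were matched to a sample by its title. The symbol ERBB2 in capitals, used for the human gene, was not found in the count table or the TPM table (0 entries each). The labels do not say which species the mutant allele came from, so values of Erbb2 are those of the mouse symbol.

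Gene lengths, positions and overlaps came from the GENCODE M21 annotation of the mm10 build, in which 53186 symbols of the count table had one gene and 106 had more than one. Libraries of one group were compared by a chi-square test over genes with at least 20 counts in a pair. All 13 pairs differed beyond sampling noise (chi-square per degree of freedom 87.9 to 504), and 0 pairs were identical, so each library was kept as 1 replicate. Across genes, Pearson's r of log2 CPM within groups was 0.907 to 0.964, with genes not independent replicates.

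Genes were tested in edgeR 4.0.16 under R 4.3.3 with TMM factors, the filterByExpr filter by group, and the robust quasi-likelihood F-test. One fit over all 14 libraries and 17933 genes, with group means only, left 9 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The SE of a log2 fold change is its size divided by the square root of F. CPM of genes are TMM-normalized, and shares and sex-linked CPM of libraries are per library total. The 8 planned comparisons set each drug group and the resistant group against vehicle, the combination against each drug alone, and the resistant group against mobocertinib. The last was the difference of differences, combination minus mobocertinib minus T-DM1 plus vehicle. T-DM1 against mobocertinib was added after the data were seen.

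Gene lists, the rule for named genes, tests and most alternatives were chosen before the data were examined. The lists described for the difference of differences, and so the genes named there, were chosen after. The 50 lists of pathway genes and cell type markers were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison. Member counts are given over all genes tested and adjusted over the list alone. A list's score in a library is the mean over members of log2 CPM minus the gene's mean over all libraries. Named genes followed a rule with 3 parts. The first took the 8 largest and 8 smallest log2 fold changes among called genes with mean log2 CPM of at least 1 and no overlap between the groups' libraries, without immune receptor segments, predicted genes and pseudogenes. The second took up to 4 called members of each described list by smallest p, or 2 where none was called. The third was a panel of 14 genes, given whatever their p against vehicle and in resistant against mobocertinib.

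Against a group at 0 counts, a fold is given as a lower bound against 3 counts over the group, and against 1 to 3 counts as a ratio with its exact 95% interval. Such intervals and bounds cover counting error only. Shares of counts in a library have 95% Wilson intervals no wider than 0.0363 percentage points.

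The procedure was tested on simulated data with the group sizes and dispersions of these libraries. In mobocertinib against vehicle, 10%, 58%, 70% and 88% of 50 genes each with 2-, 4-, 8- and 16-fold changes were called, with 5 false calls. In the combination against mobocertinib, these shares were 6%, 66%, 76% and 90%, with 1 false call. A moved list was called in both, and 0 of 50 unmoved lists was. Genes were simulated independently of each other, so this does not check camera for lists whose genes move together.

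Alternatives for each comparison were upper-quartile or median-ratio (RLE) factors, no filter beyond 1 count, a filter at 1 CPM in 3 libraries, no robust estimation, glmTreat against a 1.5-fold change, limma-voom, DESeq2 1.42.0, limma-trend on log2(TPM + 1) of genes with a TPM of 1 in 2 libraries, the compared groups alone, a covariate of non-tumor cell content, and leaving out each library in turn. That covariate was the first principal component of 82 marker genes of normal lung cells. A planned term for Y-linked transcripts, entered as their presence at 1 CPM in a library, could not be fitted because it was collinear with the groups, with a rank of 5 in 6 columns. Alternatives added after the data were seen were dropping genes on X and Y, a term for the level of Y-linked transcripts as log2(CPM + 1) in resistant against mobocertinib, leaving out each library for the lists, and per-library offsets from smooths (mgcv 1.9.3, basis size 6) of counts on transcript length and GC over 14900 protein-coding genes. Lists were also tested with an estimated correlation, with fry, and on the fit with offsets, the last added after the data were seen. Tables and plots were made in Python 3.11.15.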

Results

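The series measured RNA in lung tumor nodules of mice whose tumors carry a HER2 exon 20 insertion, YVMA, in the kinase domain of this ERBB-family receptor. Nodules came from mice given long-term vehicle (n = 2), mobocertinib (n = 3), T-DM1 (n = 3) or both drugs (n = 3), and from mice whose tumors had become resistant to mobocertinib alone (n = 3). Mobocertinib is a tyrosine kinase inhibitor of EGFR and HER2 exon 20 mutants, and T-DM1 is an antibody to HER2 that carries a microtubule poison. Library totals were 24.6 and 24.9 M counts in vehicle, 20.3, 23.1 and 24.8 M in mobocertinib, 22.3, 31.3 and 23.1 M in T-DM1, 22.7, 23.6 and 24.0 M in the combination and 22.4, 22.8 and 19.3 M in resistant nodules.

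Both vehicle libraries stood apart from the other 12 in the kinds of RNA they held. Messenger RNAs under 1 kb took 25.6% and 30.9% of vehicle counts and 6.78% to 11.9% elsewhere. Those over 5 kb took 6.12% and 4.51% in vehicle and 12.5% to 20.0% elsewhere, and ribosomal protein genes took 20.7% and 21.6% against 3.79% to 7.79%. The ribosomal RNA gene CT010467.1 held 1.88% and 5.32% of vehicle counts and 0.0887% to 0.807% elsewhere. Genes with a count numbered 20241 and 17279 in vehicle and 20532 to 23108 elsewhere. The Wilson intervals of these shares cover counting error only. In the comparisons with vehicle, medians adjusted for transcript length and GC content in each library, called length-corrected here, stand beside those of the gene lists.

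**Figure D1:**
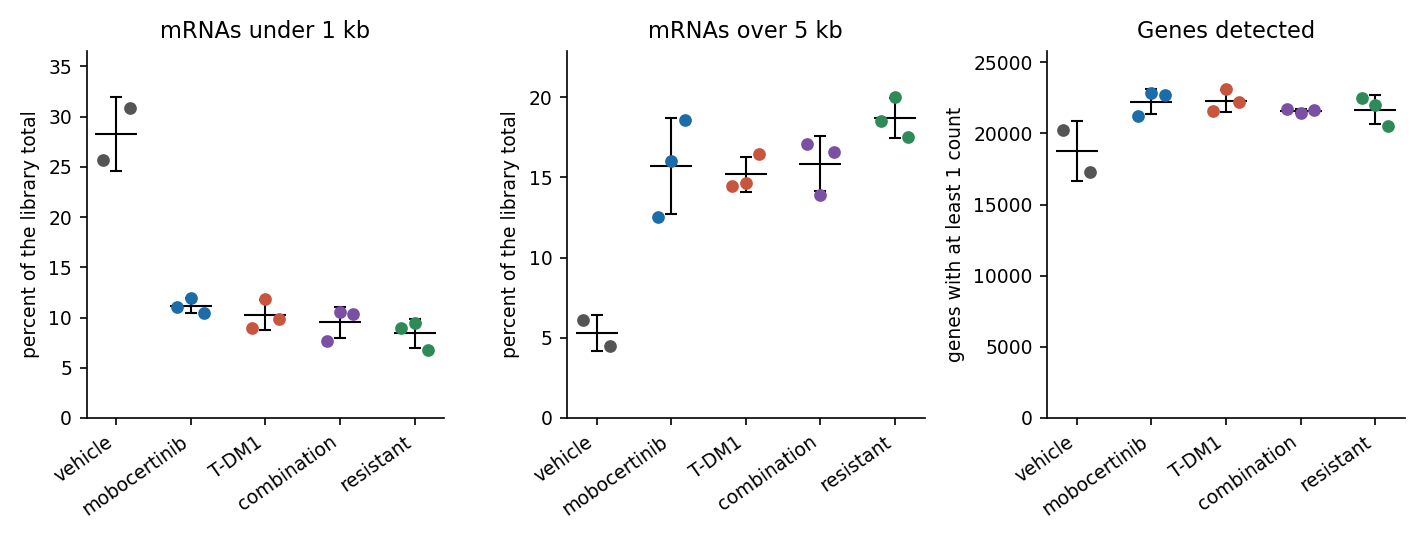
Share of the library total in messenger RNAs under 1 kb and over 5 kb (percent) and number of genes with a count, per library by group, with bars for the group mean ± SD. Short messenger RNAs took 25.6% and 30.9% of the counts in the vehicle libraries and at most 11.9% in the others.

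Changes are log2 fold changes ± SE, group levels are mean ± SD of normalized CPM with the n given above, and every adjusted p of a gene is from edgeR. On the mm10 build, Dusp6 lies on chromosome 10 (99263231 to 99267489), Etv4 on 11 (101769742 to 101785371), Cdc20 on 4 (118432901 to 118437352), Bcl6 on 16 (23965052 to 23988852), Cox7a2 on 9 (79755361 to 79759878), Ddx3y on Y (1260771 to 1286629) and Xist on X (103460366 to 103483254). The strand setting of the counting is not given in the sources used here, so values of genes that share exon bases with a neighbor are uncertain. Among the genes given in this text, 12.6% to 61.5% of exon bases were shared in Dusp5, Ccnd1, Cd274, Nppa, Xist, Cyp2f2 and Zfas1, 7.8% in Foxo1 and 8.7% in Ifi30. Rpl34 has copies elsewhere in the genome, so it is uncertain as well. A term for non-tumor cell content was lowest in both vehicle libraries, and 68.2% of its variance lay between the groups. It made the design's SE 1.37 to 1.73 times as large against vehicle, so the counts and calls it leaves there do not separate cell content from the vehicle group.

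Mobocertinib against vehicle asked how tumors under the inhibitor differ from untreated ones. Cell-cycle genes were lower in all 3 mobocertinib nodules than in both vehicle nodules. Cdc20, an activator of the anaphase-promoting complex, fell by 3.16 ± 0.375 (adjusted p = 0.000268), from 23.8 ± 0.609 to 2.65 ± 0.989 CPM. Cdk1, the kinase that drives entry into mitosis, changed by −3.16 ± 0.541 (adjusted p = 0.00123), and Birc5, the survivin gene, by −4.23 ± 0.704 (adjusted p = 0.00105). Of 22 proliferation genes, 18 fell and none rose (20 lower when adjusted over the list alone), with a median of −2.58 (camera adjusted p = 1.3e-08; adjusted p = 0.77 with an estimated correlation). With length correction 18 were lower, with a median of −2.48, while short messenger RNAs held at least 25.6% of vehicle counts. Without vehicle 1 or mobocertinib 1, 11 members were called, and without mobocertinib 3, 10 were. The median was −0.34 from TPM, where the median of all genes was 1.11.

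Genes turned on by ERK signaling were lower as well. Dusp6, a phosphatase that ERK induces and that acts back on it, fell by 2.54 ± 0.275 (adjusted p = 0.000261), from 225 ± 10.8 to 38.5 ± 7.47 CPM. Etv4, a transcription factor downstream of ERK, changed by −4.40 ± 0.713 (adjusted p = 0.000906), from 49.1 ± 10.4 to 2.33 ± 0.745 CPM. Dusp5, a nuclear phosphatase of ERK, changed by −2.57 ± 0.322 (adjusted p = 0.000313). Of 19 ERK output genes, 6 fell and none rose (6 lower and 1 higher when adjusted over the list alone), the median was −0.85, and all 3 mobocertinib nodules scored below both vehicle nodules. The list was called by camera (adjusted p = 0.0126; adjusted p = 0.77 with an estimated correlation), but not without vehicle 1 (adjusted p = 0.0687), where 3 members were lower over the list alone. Length correction gave a median of −0.90, and the TPM values turned the direction, with a median of 0.58 where that of all genes was 1.11.

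FOXO target genes, which are held down while PI3K and AKT signal, were higher in all 3 mobocertinib nodules. Bcl6, a transcriptional repressor, rose by 2.32 ± 0.307 (adjusted p = 0.000367), the insulin receptor gene Insr by 2.05 ± 0.28 (adjusted p = 0.000405), and Foxo3 by 1.99 ± 0.289 (adjusted p = 0.000504). Pdk4, a kinase that limits pyruvate oxidation, rose by 3.70 ± 0.594 (adjusted p = 0.000862). Of 15 members, 10 rose (10 when adjusted over the list alone), with a median of 1.72 (camera adjusted p = 3.25e-06; adjusted p = 0.153 with an estimated correlation). After length correction 8 were higher and the median was 0.81, beside vehicle counts of which at least 25.6% came from short messenger RNAs. The receptor genes Erbb3 and Egfr rose by 2.51 ± 0.532 (adjusted p = 0.00396) and 3.19 ± 0.706 (adjusted p = 0.00504), but Egfr did not pass by limma-voom, from TPM or with a term for non-tumor cell content.

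**Figure D2:**
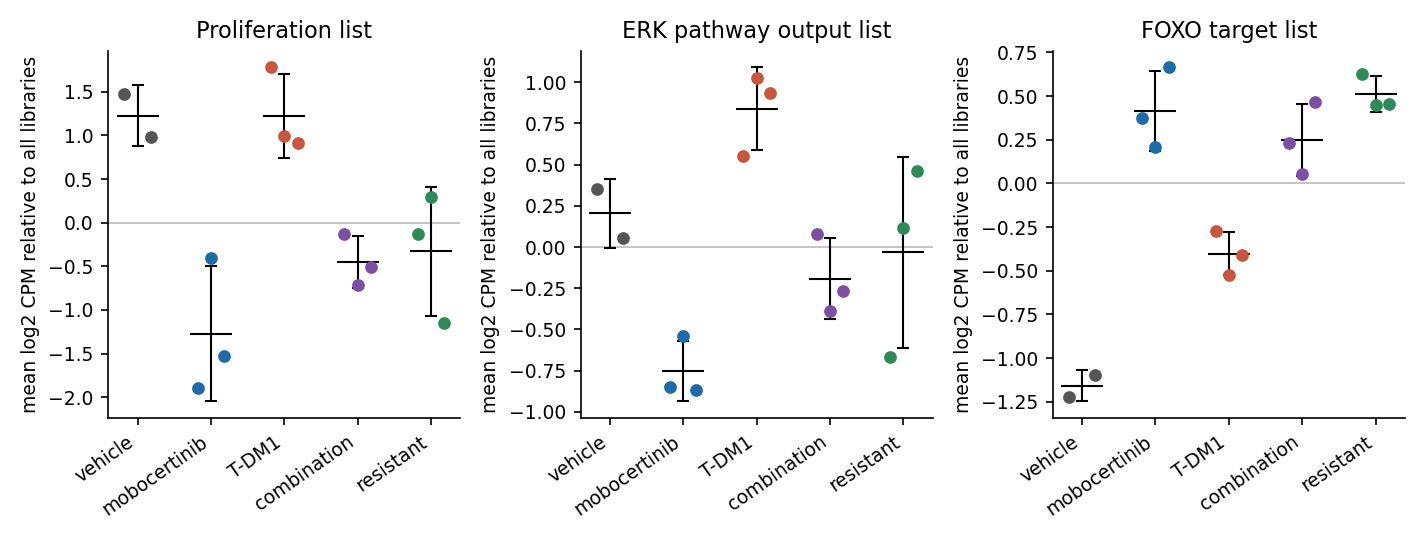
Score of the proliferation, ERK output and FOXO target lists in each library (mean over members of log2 CPM minus the gene's mean over all libraries), by group, with bars for the group mean ± SD. The mobocertinib nodules averaged −1.27 for proliferation and −0.753 for ERK output, and the T-DM1 nodules 1.23 and 0.839.

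Genes of oxidative phosphorylation were lower than in vehicle, and this group moved with the share of short messenger RNAs. Of 23 members, 17 fell and 1, Sdha, rose (the same counts when adjusted over the list alone), with a median of −1.72 (camera adjusted p = 8.24e-09; adjusted p = 0.77 with an estimated correlation). Without vehicle 1, 2 members rose. Cox7a2, a short subunit of cytochrome c oxidase, fell by 2.92 ± 0.321 (adjusted p = 0.000261), from 1445 ± 189 to 191 ± 31.4 CPM. The length-corrected median was 0.07, with 3 higher and 6 lower, and the list was not called (adjusted p = 0.158).

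Markers of other cells moved in both directions. Of 17 alveolar macrophage markers, 7 fell (7 when adjusted over the list alone; median −2.14, camera adjusted p = 0.00131; adjusted p = 0.776 with an estimated correlation). They included Fabp4 at −2.96 ± 0.595 (adjusted p = 0.00299) and Fabp5 at −2.60 ± 0.534 (adjusted p = 0.00337), which code for fatty acid binding proteins. Length correction left 4 lower, with a median of −1.39, and 3 members were called without vehicle 2. Of 20 endothelial markers, 10 rose (10 when adjusted over the list alone; median 1.18, camera adjusted p = 0.0075; adjusted p = 0.838 with an estimated correlation), and the list was not called without vehicle 1 (adjusted p = 0.0687). Cdh5, the cadherin of endothelial junctions, rose by 3.46 ± 0.602 (adjusted p = 0.00135), and the length-corrected median was 1.12. Of 12 genes of MHC class II presentation, 8 fell (8 when adjusted over the list alone; median −1.70, camera adjusted p = 0.00334; adjusted p = 0.77 with an estimated correlation). Length correction left 4 lower, with a median of −1.01; 4 were called without vehicle 1 or mobocertinib 1 and 2 without vehicle 2. The club cell enzyme gene Cyp2f2 rose by 4.98 ± 0.841 (adjusted p = 0.00114), from 220 ± 10.7 to 6923 ± 4762 CPM.

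Among the largest changes were those of 3 lower genes. Ccl17, a chemokine of dendritic cells, changed by −7.79 ± 0.77 (adjusted p = 0.000261), Cd177, a neutrophil surface gene, by −6.20 ± 1.11 (adjusted p = 0.00172), and Pf4, a chemokine of platelets and megakaryocytes, by −6.03 ± 0.964 (adjusted p = 0.000881). Several genes had 0 or 1 counts in vehicle. Aff3 was at least 71.1-fold and Gpc6 at least 30.9-fold higher, and Tmod2 had a ratio of 193.6 (95% counting interval 34.6 to 7662). Of the panel, Erbb2 at 1.38 ± 0.476 (adjusted p = 0.0411), Mki67 at −2.16 ± 0.651 (adjusted p = 0.023) and Sftpc, a surfactant gene of alveolar type 2 cells, at −3.06 ± 1.03 (adjusted p = 0.0366) passed. Erbb2 did not pass without vehicle 1 (adjusted p = 0.113), vehicle 2 (0.139), mobocertinib 1 (0.0713) or mobocertinib 2 (0.0842), nor Mki67 without vehicle 2 (0.127), mobocertinib 1 (0.0675) or mobocertinib 3 (0.0828). Sftpc did not pass without vehicle 1 (0.0552), vehicle 2 (0.153), mobocertinib 1 (0.104), 2 (0.0772) or 3 (0.0779). Panel genes that did not pass were Etv5 (−2.02), Ccnd1 (−0.66), Myc (−1.22), Top2a (−1.60), Ager (−0.83), Cd8a (2.33) and Cd274 (−1.31).

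Across 17933 genes, 5905 passed between mobocertinib and vehicle, 3015 higher and 2890 lower (2667 and 3326 with upper-quartile factors, 2487 and 2990 by limma-voom), and 16 of the 50 lists were called, none of them with an estimated correlation. The groups' libraries did not overlap for 10645 genes, where chance gives 20% of genes. With a term for non-tumor cell content 1175 genes passed, against a 1.5-fold threshold 3839, from TPM 9158 with a median over all genes of 1.11, and without vehicle 2, 3182. The length-corrected fit called 4129 of 14900 genes, 3004 of them as before, and 55.7% of messenger RNAs under 1 kb fell while 40.7% of those over 5 kb rose. Etv4, Pdk4, Fabp5, Cd177, Aff3, Erbb2, Mki67 and Sftpc did not pass with the content term, Dusp5, Fabp4, Fabp5, Mki67 and Sftpc from TPM, and Erbb2 and Sftpc after length correction or against the 1.5-fold threshold.

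T-DM1 against vehicle asked the same of tumors under the antibody conjugate. Cell-cycle genes showed no shared direction, while feedback genes of ERK, ERBB genes and interferon-response genes included several at higher levels. None of the 22 proliferation genes was called by edgeR, over all genes or adjusted over the list alone (median −0.046, camera adjusted p = 0.858), and Mki67, the Ki-67 gene, stood at 27.8 ± 9.46 against 16.1 ± 3.27 CPM (0.79 ± 0.663, adjusted p = 0.379; −0.38 after length correction). The length-corrected proliferation median was −0.067, and TPM gave 1.08, where the median of all genes was 1.17. Of 19 ERK output genes, 4 rose (4 when adjusted over the list alone; median 0.46, camera adjusted p = 0.364), among them Spred2, an inhibitor of the pathway, at 2.10 ± 0.349 (adjusted p = 0.0011). The length-corrected ERK median was 0.74, with 5 higher, and without vehicle 2, 2 were called. Dusp6 stood at 161 ± 19.3 CPM (−0.48 ± 0.271, adjusted p = 0.187).

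ERBB receptor and ligand genes scored higher in all 3 T-DM1 nodules than in both vehicle nodules. Nrg1, a ligand of ERBB3, rose by 5.56 ± 0.893 (adjusted p = 0.000889), from 0.269 ± 0.0404 to 12.9 ± 7.74 CPM. Egfr rose by 4.12 ± 0.736 (adjusted p = 0.00164) and Lrig1, a negative regulator of these receptors, by 2.25 ± 0.415 (adjusted p = 0.00198). Of 15 members, 6 rose (6 when adjusted over the list alone; median 1.24, camera adjusted p = 0.0265; adjusted p = 0.954 with an estimated correlation). Without vehicle 2, 3 were called, and without vehicle 1 the list was not (adjusted p = 0.057). With length correction 6 were higher, with a median of 1.39.

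Interferon-response genes also scored higher in each T-DM1 nodule than in both vehicle nodules. Oasl2, an interferon-induced antiviral gene, rose by 3.51 ± 0.619 (adjusted p = 0.00153), from 6.74 ± 0.872 to 76.8 ± 42.1 CPM. Gbp2, a guanylate-binding protein gene, rose by 3.12 ± 0.575 (adjusted p = 0.00197), and Ddx58, which codes for the RNA sensor RIG-I, by 2.11 ± 0.447 (adjusted p = 0.00427). None of the 3 passed with a term for non-tumor cell content. Of 23 members, 9 rose (9 when adjusted over the list alone; median 1.86, camera adjusted p = 0.00258; adjusted p = 0.954 with an estimated correlation). Without vehicle 1 or vehicle 2, 5 were called, without T-DM1 2, 16 over the list alone, and without vehicle 1 the list was not called (adjusted p = 0.057). The length-corrected median was 1.99, with 13 higher.

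FOXO targets were higher than in vehicle in all 3 T-DM1 nodules, with Bcl6 at 1.84 ± 0.301 (adjusted p = 0.000973) and Foxo1 at 1.51 ± 0.246 (adjusted p = 0.000981). Of 15 members, 8 rose and 1 fell (the same counts when adjusted over the list alone; median 1.21, camera adjusted p = 0.0327; adjusted p = 0.915 with an estimated correlation). Without vehicle 2, 5 rose, and without vehicle 1 the list was not called (adjusted p = 0.169). The length-corrected median was 0.41, with 1 higher and 1 lower (adjusted p = 0.534). Of 23 oxidative phosphorylation genes, 17 fell and 1 rose (17 and 2 when adjusted over the list alone; median −1.75, camera adjusted p = 7.7e-10; adjusted p = 0.915 with an estimated correlation). Their length-corrected median was −0.075 (adjusted p = 0.0679), beside vehicle counts of which at least 25.6% came from short messenger RNAs.

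Of 17 alveolar macrophage markers, 8 fell in T-DM1 (9 when adjusted over the list alone; median −2.29, camera adjusted p = 0.00116; adjusted p = 0.954 with an estimated correlation), with a length-corrected median of −1.28 and 3 lower. Without vehicle 2, 2 were called, without T-DM1 1 or T-DM1 3, 5, and without T-DM1 2, 14 over the list alone. Endothelial Cdh5 rose by 3.34 ± 0.599 (adjusted p = 0.00166). Among the largest changes, Wfdc17, a gene of myeloid cells, changed by −6.16 ± 0.702 (adjusted p = 0.000228), from 2157 ± 1727 to 30.1 ± 10.6 CPM, and Ccl17 by −6.01 ± 0.71 (adjusted p = 0.000238). Zfas1, a noncoding host of small nucleolar RNAs, fell by 4.95 ± 0.567 (adjusted p = 0.000228), from 1572 ± 753 to 50.8 ± 18.4 CPM. Gpc6 was at least 72.6-fold and Aff3 at least 25.7-fold higher. Xist changed by 8.19 (adjusted p = 0.0225), with 44.1, 21.3 and 0.562 CPM of the library total in T-DM1 1, 2 and 3. It did not pass without a filter, by limma-voom or with a term for non-tumor cell content. Of the panel, Erbb3 at 1.94 ± 0.517 (adjusted p = 0.0137) and Sftpc at −2.94 ± 1.02 (adjusted p = 0.0442) passed, but not Erbb3 without vehicle 2 (adjusted p = 0.11). Sftpc did not pass without vehicle 1 (adjusted p = 0.0639), vehicle 2 (0.177), T-DM1 1 (0.106) or T-DM1 3 (0.132). Erbb2 (1.21), Etv4 (−1.82), Etv5 (−0.84), Ccnd1 (1.28), Myc (0.55), Top2a (0.76), Ager (−0.63), Cd8a (2.79) and Cd274 (−0.91) did not pass.

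Between T-DM1 and vehicle, 5676 genes passed, 2996 higher and 2680 lower (2589 and 3152 with upper-quartile factors, 2366 and 2822 by limma-voom), and 9 lists were called, none of them with an estimated correlation. Libraries did not overlap for 10429 genes, where chance gives 20%. With a term for non-tumor cell content 999 genes passed, against a 1.5-fold threshold 3643, from TPM 9629, on the compared groups alone 3745, and without vehicle 2, 2750. The length-corrected fit called 3776 of 14900 genes, 2752 of them as before, with median changes of −1.57 under 1 kb and 1.03 over 5 kb. Bcl6, Egfr, Aff3 and Sftpc did not pass with the content term either, Foxo1, Erbb3 and Sftpc after length correction, Aff3 and Sftpc from TPM and Aff3 by limma-voom.

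The combination against vehicle measured tumors given both drugs. As under mobocertinib alone, cell-cycle genes, Dusp6 and Etv4 were lower and FOXO targets higher than in vehicle in all 3 nodules. Dusp6 changed by −2.22 ± 0.273 (adjusted p = 0.000209), to 48.1 ± 6.54 CPM, and Etv4 by −3.63 ± 0.691 (adjusted p = 0.00197). Cdc20 changed by −2.69 ± 0.369 (adjusted p = 0.000321) and Rrm2, a subunit of the enzyme that makes deoxynucleotides, by −2.66 ± 0.539 (adjusted p = 0.00282). Of 22 proliferation genes, 11 fell (13 when adjusted over the list alone; median −1.92, camera adjusted p = 0.000224; adjusted p = 0.956 with an estimated correlation). Without vehicle 2 or combination 3, 7 were called, and without combination 2, 6. The length-corrected median was −1.79, with 11 lower, and TPM turned it to 0.08 where the median of all genes was 1.18.

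Of 19 ERK output genes, 5 fell and 2 rose in the combination (6 and 2 when adjusted over the list alone), and the list was not called (median −0.31, camera adjusted p = 0.315), with a TPM median of 1.38 and a length-corrected one of −0.27 (2 higher and 7 lower). Without vehicle 1, vehicle 2, combination 2 or combination 3, 3 fell, and without vehicle 2 or combination 1, 1 rose. Of 15 FOXO targets, 9 rose (10 when adjusted over the list alone; median 1.77, camera adjusted p = 8.84e-05; adjusted p = 0.307 with an estimated correlation), including Bcl6 at 2.40 ± 0.308 (adjusted p = 0.000246). Their length-corrected median was 0.85, with 8 higher. Egfr rose by 4.07 ± 0.734 (adjusted p = 0.00146) and Erbb3 by 2.48 ± 0.531 (adjusted p = 0.00389). Oxidative phosphorylation genes had 17 lower and 1 higher (the same when adjusted over the list alone; median −1.82, camera adjusted p = 2.18e-09; adjusted p = 0.831 with an estimated correlation). Their length-corrected median was 0.085 (adjusted p = 0.168), beside vehicle counts of which at least 25.6% came from short messenger RNAs.

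Alveolar macrophage markers were lower in the combination in 11 of 17 cases (11 when adjusted over the list alone; median −2.50, camera adjusted p = 0.000287; adjusted p = 0.956 with an estimated correlation), with a length-corrected median of −2.11 and 7 lower. Without vehicle 2, 5 were called, and without combination 2, 6. Tigit, an inhibitory receptor of T and NK cells, rose by 7.38 ± 1.21 (adjusted p = 0.000854), from 0.111 ± 0.158 to 17.9 ± 6.49 CPM, a ratio of 182 (95% counting interval 62.2 to 884). Ccl17 changed by −6.98 ± 0.742 (adjusted p = 0.000154) and Pf4 by −5.64 ± 0.947 (adjusted p = 0.00101). Gpc6 was at least 45.2-fold and Aff3 at least 36.4-fold higher. Of the panel, Erbb2 (1.69 ± 0.482, adjusted p = 0.0172) passed, but not without vehicle 1 (0.0654), vehicle 2 (0.0807) or combination 1 (0.0604). Cd274, the PD-L1 gene (−1.53 ± 0.506, adjusted p = 0.0327), did not pass without vehicle 2 (0.294), combination 1 (0.0909), 2 (0.0892) or 3 (0.0526). Sftpc (−3.25 ± 1.03, adjusted p = 0.0279) did not pass without vehicle 2 (0.125), combination 1 (0.0908) or 2 (0.0804), nor Etv5 (−2.35 ± 0.852, adjusted p = 0.0481) without any of the 5 libraries (0.0916 to 0.137). Mki67 (−1.09), Top2a (−0.71), Ccnd1 (0.15), Myc (−0.49), Ager (−0.47) and Cd8a (2.74) did not pass.

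**Figure D3:**
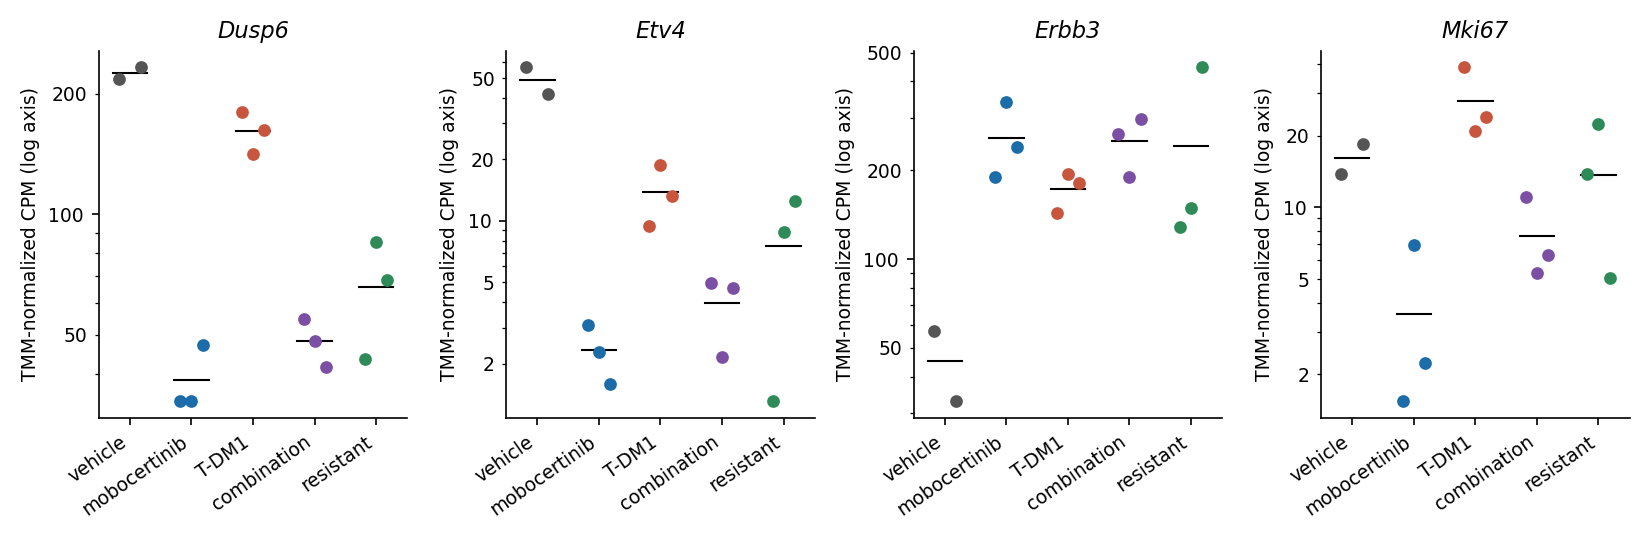
Normalized CPM of Dusp6, Etv4, Erbb3 and Mki67 in each library by group, on a log axis, with a line at the group mean. Dusp6 averaged 225 CPM in vehicle, 38.5 in mobocertinib, 161 in T-DM1, 48.1 in the combination and 65.8 in resistant nodules.

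Between the combination and vehicle, 6278 genes passed, 3165 higher and 3113 lower (2703 and 3589 with upper-quartile factors, 3102 and 3185 with RLE factors, 2748 and 3154 by limma-voom), and 8 lists were called, none of them with an estimated correlation. Libraries did not overlap for 11322 genes, where chance gives 20%. With a term for non-tumor cell content 2461 genes passed, from TPM 9504, and without vehicle 2, 3630. The length-corrected fit called 4291 of 14900 genes, 3124 of them as before, with median changes of −1.80 under 1 kb and 1.01 over 5 kb. Etv4, Cd274, Sftpc, Erbb2 and Etv5 did not pass with the content term, Erbb2 and Sftpc after length correction, and Aff3, Cdc20, Rrm2, Dusp6, Etv4, Cd274, Sftpc and Etv5 from TPM.

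These comparisons share the 2 vehicle libraries, so overlap is partly built in. Mobocertinib and T-DM1 had 2356 genes higher and 2165 lower in common and 0 in opposite directions, where independent lists would give 504 and 432. In 20 simulations with vehicle shared but no drug effect or vehicle shift, mean overlap was 0 genes each way, which that largely fixes. Their r of fold changes was 0.655 against a measured 0.892 and covariance 0.531 against 3.87, across genes, not independent replicates. A vehicle shift alone could raise both, so neither shows a drug effect. Mobocertinib and the combination had 2728 and 2621 in common.

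The combination against mobocertinib asked what the antibody conjugate added. No single gene passed, but 22 lists, of immune cells among them, were called by camera alone. All 22 proliferation genes had higher estimates in the combination, with a median of 0.81 (camera adjusted p = 3.18e-13; adjusted p = 0.349 with an estimated correlation); Birc5 was at 1.30 ± 0.614 (adjusted p = 1). ERK output genes had a median of 0.54 with 17 of 19 positive (camera adjusted p = 2.68e-09; adjusted p = 0.149 with an estimated correlation), and all 3 combination nodules scored above the mobocertinib nodules. Dusp5 stood at 9.28 ± 1.58 against 5.28 ± 1.47 CPM. Neither list had a member called over all genes or adjusted over the list alone, except 4 proliferation genes without mobocertinib 2. Mobocertinib 2 scored above 2 of the combination nodules for proliferation.

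Squamous and basal cell genes had a median of 1.47 in the combination against mobocertinib (12 of 14 positive, camera adjusted p = 7.17e-13; adjusted p = 0.149 with an estimated correlation), and Krt17, a basal keratin, stood at 25.3 ± 20.2 against 3.44 ± 1.59 CPM. None was called adjusted over the list alone, except 4 without combination 2. Among tubulins and microtubule regulators, Tubb2b stood at 11.6 ± 2.36 against 3.36 ± 0.772 CPM (1.78 ± 0.404, adjusted p = 1). It was the 1 member called adjusted over the list alone (2 without mobocertinib 1), with a list median of 0.22 (camera adjusted p = 2.14e-06; adjusted p = 0.113 with an estimated correlation). Mean list scores were −0.307 in mobocertinib, 0.049 in the combination, 0.228 in T-DM1 and 0.246 in vehicle. Heart and skeletal muscle genes had a median of −3.84 (camera adjusted p = 7.17e-13; adjusted p = 0.279 with an estimated correlation; 0 called adjusted over the list alone). Their scores overlapped, with mobocertinib 1 at −1.87 below combination 1 at −0.222, while mobocertinib 2 and 3 stood at 1.81 and 3.65. Nppa, made in heart atria, had 1 count over the 3 combination libraries and a ratio of 2582 (95% counting interval 463 to 102000) in favor of mobocertinib.

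Cytotoxic and NK (median 0.80, camera adjusted p = 3.58e-05), T (0.40, 0.0037), dendritic (0.56, 0.000742) and neutrophil markers (0.50, 0.000305) had higher estimates in the combination and erythroid markers lower ones (−1.36, 7.17e-13). With an estimated correlation these had adjusted p = 0.401, 0.712, 0.441, 0.401 and 0.113. The first 3 were not called without mobocertinib 1, and neutrophil markers not without mobocertinib 2 or combination 3.

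By edgeR 0 genes passed between the combination and mobocertinib, where 262 had an unadjusted p under 0.05, by DESeq2 1 did (366 unadjusted), and by limma-voom (234) and from TPM (201) 0. None of the 22 lists was called with an estimated correlation, and libraries did not overlap for 1200 genes, where chance gives 10%.

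The combination against T-DM1 asked what the inhibitor added. All 22 proliferation genes had lower estimates in the combination, with a median of −1.73 (camera adjusted p = 3.47e-30; adjusted p = 0.135 with an estimated correlation), and all 3 nodules scored below all 3 T-DM1 nodules. None was called over all genes and 19 adjusted over the list alone, which became 7 without T-DM1 1 or combination 2 and 9 without combination 3. Cdc20 stood at 3.69 ± 0.756 against 16.8 ± 1.73 CPM (−2.19 ± 0.342, adjusted p = 0.226). ERK output genes had a median of −1.09, with 6 lower adjusted over the list alone (3 without combination 2), and the list was also called with an estimated correlation (adjusted p = 0.0461; camera adjusted p = 2.78e-16). Dusp6 stood at 48.1 ± 6.54 against 161 ± 19.3 CPM (−1.74 ± 0.252), with the smallest adjusted p of all genes, 0.201.

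FOXO targets were positive in 15 of 15 cases between the combination and T-DM1, with a median of 0.54, and this list too was called with an estimated correlation (adjusted p = 0.0246; camera adjusted p = 2.15e-10; 0 called adjusted over the list alone). Pik3ip1, an inhibitor of PI3K, was at 0.93 ± 0.315 (adjusted p = 0.901). Hypoxia and glycolysis genes had a median of −0.64 (camera adjusted p = 2.5e-08; adjusted p = 0.135 with an estimated correlation), with lactate dehydrogenase gene Ldha at 812 ± 63.4 against 1600 ± 171 CPM. Over the list alone 2 were called, 0 without T-DM1 1, T-DM1 3 or any combination library and 4 without T-DM1 2. Interferon-response genes had a median of −0.89 (camera adjusted p = 3.47e-07; adjusted p = 0.454 with an estimated correlation), with 0 members called adjusted over the list alone and 8 without T-DM1 2.

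By edgeR 0 genes passed between the combination and T-DM1, where 915 had an unadjusted p under 0.05, by DESeq2 75 did, 8 higher and 67 lower, and by limma-voom (938 unadjusted) and from TPM (793) 0. Camera called 20 lists, of which 2 were called with an estimated correlation, and libraries did not overlap for 2908 genes, where chance gives 10%.

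Resistant against mobocertinib nodules asked what differed once tumors had escaped the inhibitor. ERK output genes had higher estimates in resistant nodules, with a median of 0.93 and 17 of 19 positive (camera adjusted p = 4.98e-07; adjusted p = 0.777 with an estimated correlation). Spred2 stood at 28.6 ± 7.53 against 11.2 ± 1.77 CPM (1.36 ± 0.292), Etv1, an ETS factor downstream of ERK, at 20.4 ± 17.9 against 4.25 ± 1.64 (2.26 ± 0.583), and Dusp6 at 65.8 ± 21.1 against 38.5 ± 7.47 (0.77 ± 0.247), each with an adjusted p of 0.622. None was called over all genes and 5 were adjusted over the list alone. That count was 0 without mobocertinib 1, 1 without mobocertinib 2 or resistant 2, 10 without resistant 1 and 2 without resistant 3. Resistant 1 scored below mobocertinib 2.

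Proliferation genes were positive in 21 of 22 cases, with a median of 1.08 (camera adjusted p = 3.77e-07; adjusted p = 0.777 with an estimated correlation) and a length-corrected median of 0.93. Mki67 stood at 13.7 ± 8.62 against 3.59 ± 2.96 CPM (1.93 ± 0.604, adjusted p = 0.622). None was called over all genes or adjusted over the list alone, except 12 over the list alone without mobocertinib 2 and 7 without resistant 3. Resistant 3, with a proliferation score of −1.14, lay below mobocertinib 2 at −0.399. Erbb2 stood at 691 ± 404 against 377 ± 99.1 CPM (0.88 ± 0.409, adjusted p = 0.622) and Erbb3 at −0.092 ± 0.429 (adjusted p = 0.959). Egfr (0.52), Etv4 (1.70), Etv5 (0.24), Ccnd1 (1.04), Myc (0.93), Top2a (1.26), Sftpc (−0.74), Ager (−1.13), Cd8a (−0.25) and Cd274 (−0.34) did not pass either.

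Dendritic cell and fibroblast markers had higher estimates in resistant nodules, and mesothelial markers and p53 targets lower ones. Mesothelial markers had a median of −0.92 (camera adjusted p = 0.00836; adjusted p = 0.777 with an estimated correlation) and were not called without mobocertinib 1 or resistant 3 (adjusted p of at most 0.0646). Dendritic cell markers had a median of 1.68 (camera adjusted p = 0.000236; adjusted p = 0.777 with an estimated correlation), with the chemokine Ccl22 at 2.43 ± 0.78, and the list was not called without resistant 1 (adjusted p = 0.125). Fibroblast markers had a median of 1.30 (camera adjusted p = 0.000489; adjusted p = 0.777 with an estimated correlation), with the matrix gene Dcn at 2.09 ± 0.862, and were not called without resistant 1 (adjusted p = 0.915). Genes of the p53 response had a median of −0.39 (camera adjusted p = 0.00139; adjusted p = 0.777 with an estimated correlation), with Phlda3, which restrains AKT, at −1.36 ± 0.447, and were not called without resistant 1 (adjusted p = 0.193). None of these lists had a member called adjusted over the list alone, while without resistant 3, 7 dendritic, 12 fibroblast and 6 p53 genes were.

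The Y-linked gene Ddx3y was the 1 gene that passed, at −7.37 ± 0.869 (adjusted p = 0.0228) and 0.135 ± 0.073 against 23.8 ± 15.8 CPM. It did not pass without mobocertinib 1 (adjusted p = 0.0523), resistant 1 (0.145), resistant 2 (0.427) or resistant 3 (0.276). In CPM of the library total, Xist, expressed from the inactive X chromosome, stood at 217, 523 and 63.8 in the resistant libraries and at most 2.59 in mobocertinib. The sum of 4 Y-linked genes was at most 0.85 in resistant libraries and at least 48.9 in mobocertinib, so sex and group coincide in this comparison. With a term for the level of Y-linked transcripts, chosen after the data had been seen, 0 genes passed, the proliferation median was −0.14 (camera adjusted p = 0.644) and the ERK median 1.19 (camera adjusted p = 0.0238; adjusted p = 0.672 with an estimated correlation). Fibroblast genes had a median of 1.56 (camera adjusted p = 0.000129, adjusted p = 0.672 with an estimated correlation), and dendritic genes (−0.94) were not called. Mesothelial genes (−1.88) and p53 targets (−0.50) were not called either, both at a camera adjusted p of 0.0506. Neither of these medians was smaller in size than without the term, so the lost calls do not show that the term removed the changes. That term made the design's SE of the comparison 2.74 times as large. Ddx3y did not pass by limma-voom, from TPM, without a filter or on the compared groups alone either. In edgeR 1394 genes had an unadjusted p under 0.05, DESeq2 called 30, 18 higher and 12 lower, and limma-voom (1154 unadjusted) and TPM 0. Camera called 13 lists, none of them with an estimated correlation, and libraries did not overlap for 1808 genes, where chance gives 10%.

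**Figure D4:**
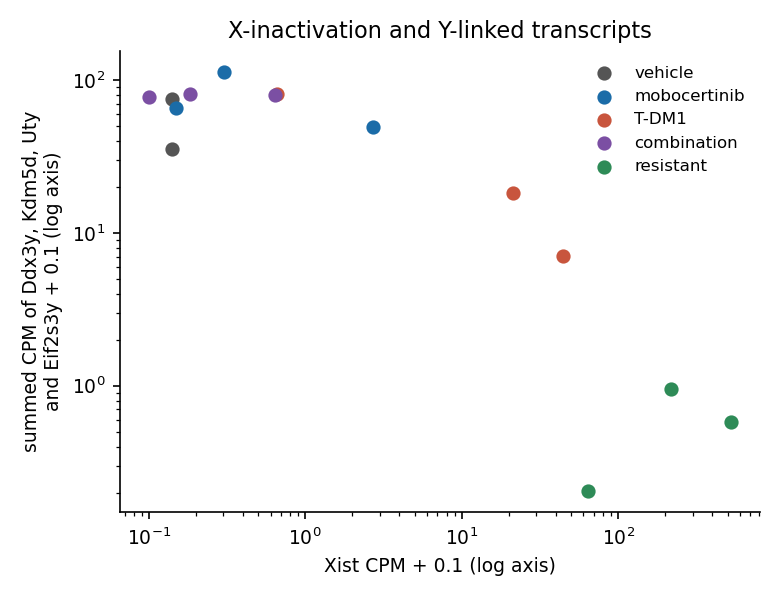
Xist against the summed Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, both in CPM of the library total plus 0.1 on log axes, with 1 point per library. The 3 resistant libraries lie at Xist of 63.8 to 523 with a Y-linked sum of at most 0.85.

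Resistant against vehicle nodules placed the resistant tumors beside untreated ones. Sex and group coincide here too, with Y-linked sums of at least 35.03 CPM of the library total in vehicle and at most 0.85 in resistant libraries. Cdc20 changed by −2.60 ± 0.368 (adjusted p = 0.000232), Dusp6 by −1.77 ± 0.271 (adjusted p = 0.000357) and Etv4 by −2.71 ± 0.671 (adjusted p = 0.00679), while Spred2 rose by 1.63 ± 0.342 (adjusted p = 0.00262). Mki67 was at −0.23 ± 0.646 (adjusted p = 0.793). Erbb2 rose by 2.25 ± 0.496 (adjusted p = 0.00347), Egfr by 3.71 ± 0.722 (adjusted p = 0.00166) and Erbb3 by 2.42 ± 0.53 (adjusted p = 0.00339). Of 22 proliferation genes, 10 fell (10 when adjusted over the list alone; median −1.39, camera adjusted p = 0.00331; adjusted p = 0.976 with an estimated correlation), or 6 without vehicle 2 and, over the list alone, 6 without resistant 3. Their length-corrected median was −1.57, and the TPM median was 0.21 where that of all genes was 1.27. Of 19 ERK output genes, 3 fell, or 5 without resistant 2, and 2 rose (the same when adjusted over the list alone), with a median of 0.054, a length-corrected one of 0.12, a mean of −0.043, and a median of −0.11 with upper-quartile factors (camera adjusted p = 0.639).

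Of 15 FOXO targets, 11 rose in resistant nodules (11 when adjusted over the list alone; median 1.98, camera adjusted p = 3.83e-05; adjusted p = 0.194 with an estimated correlation), led by Foxo3 at 2.51 ± 0.296 (adjusted p = 8.83e-05). Their length-corrected median was 0.88, with 9 higher. Of 17 alveolar macrophage markers, 10 fell (10 when adjusted over the list alone; median −2.37, camera adjusted p = 0.000908; adjusted p = 0.976 with an estimated correlation), or 6 without vehicle 2, and the length-corrected median was −1.61. Xist had a ratio of 3822 (95% counting interval 1058 to 31560), and Ddx3y fell by 7.23 ± 0.886 (adjusted p = 0.000101). Myh11, the smooth muscle myosin gene, rose by 6.85 ± 1.17 (adjusted p = 0.000747), and Aff3 was at least 91.1-fold higher. Rpl34, a short ribosomal protein gene, fell by 5.84 ± 0.737 (adjusted p = 0.00012), from 6819 ± 1395 to 119 ± 55.3 CPM, beside vehicle libraries in which ribosomal protein genes took at least 20.7% of counts. Cd274 (−1.65 ± 0.506, adjusted p = 0.0204) did not pass without vehicle 2 (0.192), resistant 1 (0.0624) or resistant 3 (0.0524), nor Sftpc (−3.81 ± 1.05, adjusted p = 0.0122) without vehicle 2 (0.0587). Etv5 (−1.78), Ccnd1 (0.38), Myc (−0.30), Top2a (−0.34), Ager (−1.96) and Cd8a (2.08) did not pass.

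Between resistant and vehicle nodules, 7357 genes passed, 3954 higher and 3403 lower (3435 and 3889 with upper-quartile factors, 3277 and 3573 by limma-voom, 9407 and 754 from TPM), and 10 lists were called, none of them with an estimated correlation. Libraries did not overlap for 9759 genes, where chance gives 20%. With a term for non-tumor cell content 1097 genes passed, on the compared groups alone 3344, and without vehicle 2, 4602. The length-corrected fit called 5030 of 14900 genes, 3661 of them as before, with median changes of −2.02 under 1 kb and 1.36 over 5 kb. Dusp6, Etv4, Spred2, Egfr, Erbb2, Xist, Myh11, Aff3, Cd274 and Sftpc did not pass with the content term, Cdc20, Dusp6, Etv4 and Cd274 from TPM, Xist by limma-voom, Sftpc after length correction and Cd274 on the compared groups alone.

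The difference of differences asked whether the drugs together moved genes by more or less than the sum of their separate changes. The lists described here, and so the genes named, were chosen after the data had been seen. These genes changed in the same direction under each drug alone, and under both by less than that sum. An offset of the vehicle libraries shared by all drug groups gives this by arithmetic, since it enters the test once with its sign turned. Against vehicle, Cox7a2 was at −2.92, −3.29 and −3.24 under mobocertinib, T-DM1 and both. Such an offset cannot be told from a drug effect here. In this test Cox7a2 was at 2.97 ± 0.426 (adjusted p = 0.00648), Cdh5 at −3.52 ± 0.731 (adjusted p = 0.0119) and Bcl6 at −1.77 ± 0.383 (adjusted p = 0.0137). Each was opposite in sign to its change under either drug. Cox7a2 did not pass after length correction, and Cdh5 and Bcl6 did not pass without vehicle 2 (adjusted p = 0.0631 and 0.071). Of 23 oxidative phosphorylation genes, 14 were higher (17, and 1 lower, when adjusted over the list alone; median 1.65, camera adjusted p = 4.57e-09; adjusted p = 0.887 with an estimated correlation), with a length-corrected median of 0.13 and a TPM median of 0.098. Endothelial markers had 7 lower (9 when adjusted over the list alone; median −1.31, camera adjusted p = 0.0084) and FOXO targets 6 lower (8; median −1.36, camera adjusted p = 0.0084), both with adjusted p = 0.887 with an estimated correlation. Without vehicle 2, 4 oxidative phosphorylation genes, 1 endothelial gene and 0 FOXO genes were called over all genes (15, 8 and 6 over each list alone). The first 2 counts were 6 and 4 without mobocertinib 3 and 9 and 3 without T-DM1 3, with 9 oxidative phosphorylation genes without combination 3 and 3 endothelial genes without combination 2. After length correction 4 and 1 members were lower, and neither list was called without vehicle 1 (adjusted p = 0.104 and 0.0655).

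In this test 2194 genes passed, 1044 higher and 1150 lower (1218 and 1015 with upper-quartile factors, 1043 and 788 by limma-voom, 245 and 6236 from TPM), and 13 lists were called, none of them with an estimated correlation. With a term for non-tumor cell content 0 genes passed in edgeR (2772 at an unadjusted p under 0.05), where DESeq2 without that term called 3801, and the length-corrected fit called 936. Without vehicle 2 the count was 409, without T-DM1 3 880, without combination 2 914, without mobocertinib 3 1094, without combination 3 1223 and without T-DM1 1 1411.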

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

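The tests of explanations in this part, the splits of the libraries included, were chosen after the results had been seen. The difference of differences was planned, but the lists and genes described for it were chosen after the data had been seen.

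The difference between the drugs' joint and separate changes against vehicle was itself tested, and 2194 of 17933 genes differed. Oxidative phosphorylation genes had a median difference of 1.65, with Cox7a2 at 2.97 ± 0.426. Endothelial markers had a median of −1.31, with Cdh5 at −3.52 ± 0.731. FOXO targets had a median of −1.36, with Bcl6 at −1.77 ± 0.383. The oxidative phosphorylation median was 0.13 after length correction, each list had an adjusted p of 0.887 with an estimated correlation, and 0 genes passed in edgeR with the content covariate (2772 unadjusted), a term lowest in both vehicle libraries, and 409 without vehicle 2.

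Against vehicle, 5676 to 7357 genes passed in each comparison, and Cox7a2 and 16 other oxidative phosphorylation genes were lower under mobocertinib. A difference in total counts was argued against. The highest vehicle total, 24.9 M counts, lay within the 19.3 to 31.3 M of the other libraries. TMM factors were 0.677 and 0.542 in vehicle and 0.988 to 1.23 elsewhere, so the fit used vehicle library sizes well below these totals. A difference in that effective depth was left open. Length or GC bias was not the whole cause, since 4129 genes passed after its correction. For the oxidative phosphorylation list that bias is a candidate explanation, as the median of the 22 members tested with and without the offsets went from −1.68 (SD over members 1.098) to 0.07 (SD 0.898), with length and GC trends taken out together and not told apart. The state or handling of the vehicle nodules' RNA cannot be told apart from an effect of treatment, because both vehicle libraries, with at least 25.6% of counts in short messenger RNAs, stood apart from all others. The difference of differences uses the same libraries, so it leaves this open too, and the labels give no value that would separate them.

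Under mobocertinib the proliferation and ERK output lists were lower, with Dusp6 at −2.54 and Cdc20 at −3.16. For the proliferation list, length and GC bias was argued against by a corrected median of −2.48. A lower share of tumor cells was left open. Markers of other cells moved apart, with alveolar macrophage genes at −2.14 and endothelial genes at 1.18, or −1.39 and 1.12 after correction. This cannot decide it, since fewer tumor cells with more of some other cells and fewer of others would give the same. The state of the vehicle libraries as the sole source was left open. In T-DM1 against mobocertinib, vehicle is in the fit but not compared. Its medians were 2.48 for proliferation and 1.77 for ERK output, the same on these 2 groups alone. They show that these 2 groups differ. They cannot show that mobocertinib lies below untreated tumors, since higher levels under T-DM1 would give the same. T-DM1 1 and T-DM1 2 held Xist at 44.1 and 21.3 and Y-linked sums of 6.99 and 18.0 CPM of the library total. Mobocertinib libraries held at most 2.59 and at least 48.9, and T-DM1 3 held 0.562 and 80.4. Sex or mixed samples thus partly coincide with this contrast. In that comparison 5 genes passed with vehicle in the fit and 0 on the 2 groups alone. Other splits of the 6 libraries gave at most 1, but 10 splits are too few for a share under 0.05. A lower output of the receptor pathway under the inhibitor may be the biological explanation, a hypothesis found and tested on the same libraries.

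In resistant against mobocertinib nodules, Ddx3y passed and the proliferation and ERK output lists stood higher. The sex of the mice is a candidate explanation for Ddx3y, with Xist of at least 63.8 CPM of the library total in resistant and at most 2.59 in mobocertinib libraries. For the lists it cannot be told apart from resistance, because a term for the presence of Y-linked transcripts left the design with a rank of 5 in 6 columns, and with their level as the term the proliferation median was −0.14 and the ERK median 1.19 at an SE 2.74 times as large. Length and GC bias was argued against by a corrected proliferation median of 0.93. The real split gave 1 gene and the highest other split 95, and 2 of the 10 splits gave at least 1, which are too few splits for a share under 0.05. The 95, with resistant 1, resistant 2 and mobocertinib 3 set against the rest, point to a structure of the samples other than the groups. Messenger RNAs over 5 kb took 18.5%, 20.0% and 18.6% of counts in these libraries and at most 17.5% in the rest. Their fibroblast scores were 2.14, 0.647 and 0.618, and at most −0.261 in the rest. Whether either is the source was not tested.

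In the combination against mobocertinib and against T-DM1, all 10 splits, the real one included, gave 0 genes, so the splits decide nothing here.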

How the results depend on the processing

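Length and GC offsets, removal of X and Y genes, the term for the level of Y-linked transcripts and the leave-one-out tests of lists were chosen after the data had been seen, the other alternatives before. Of 311 gene values named, 215 passed, and over the alternatives these gave 3914 pairs of value and setting. In 3532 pairs direction and side of the threshold were kept, in 373 the gene no longer passed and in 9 the direction turned. With RLE or upper-quartile factors all 215 genes passed in the same direction, and without robust estimation 214 did. With the content covariate 107 no longer passed, from TPM 53 and with the offsets 29. Where not stated, the cause was not tested. The planned term for the presence of Y-linked transcripts was collinear with the groups and not run. No paired analysis was possible because the replicate numbers pair no libraries. Where a left-out library leaves 1 vehicle library, that library is assumed to vary like the other groups.

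Gene counts moved by more than 1.5 times as follows. With the content covariate they were 1175 in mobocertinib against vehicle, 999 in T-DM1 against vehicle, 2461 in the combination against vehicle, 1097 in resistant against vehicle, 2 in resistant against mobocertinib and 0 for the difference of differences in edgeR (2772 unadjusted). Both vehicle libraries had the lowest content scores (at most −1.33, with −0.792 or more elsewhere), 68.2% of the score's variance lay between groups, and the design's SE was 1.37 to 1.73 times as large wherever vehicle took part, so these drops are not a measure of cell content. From TPM they were 9158, 9629 and 9504 in the 3 drug groups against vehicle, 6481 for the difference of differences, 12 in T-DM1 against mobocertinib and 0 in resistant against mobocertinib. There 94.7%, 94.3% and 94.4% of drug calls were higher, with medians over all genes of 1.11, 1.17 and 1.18, so a shift of the whole scale goes with these counts. In resistant against vehicle 92.6% were higher, with a median over all genes of 1.27, and for the difference of differences 3.78%, with a median of −1.11. The side with more calls depended on the processing in all 5 of these results. With upper-quartile factors 44.5%, 45.1%, 43.0% and 46.9% were higher in mobocertinib, T-DM1, the combination and resistant nodules against vehicle and 54.5% for the difference of differences, from 51.1%, 52.8%, 50.4%, 53.7% and 47.6%. By limma-voom these were 45.4%, 45.6%, 46.6%, 47.8% and 56.96%. A filter at 1 CPM in 3 libraries also turned it in the 3 drug groups (47.5%, 49.3% and 47.6%) and the difference of differences (53.5%), the compared groups alone in T-DM1 (47.0%) and resistant nodules (49.2%), RLE factors in the combination (49.3%) and the 1.5-fold threshold in the combination (49.2%) and the difference of differences (50.7%). For the last, leaving out vehicle 2, T-DM1 2, T-DM1 3, combination 1 or combination 2 turned it as well (50.2% to 51.9%). Against a 1.5-fold threshold, which asks for more by construction, they were 3839, 3643 and, for the difference of differences, 998. By DESeq2 they were 1 in the combination against mobocertinib, 75 in the combination against T-DM1, 30 in resistant against mobocertinib, 3801 for the difference of differences and 428 in T-DM1 against mobocertinib. On the compared groups alone, with fewer samples, they were 3745 in T-DM1 and 3344 in resistant against vehicle, 3352 for the difference of differences and 0 in both resistant and T-DM1 against mobocertinib. With the offsets, where 14900 genes are tested, they were 3776 in T-DM1 against vehicle, 936 for the difference of differences, 13 in T-DM1 against mobocertinib and 2 in resistant against mobocertinib. On the same genes without the offsets the first 2 were 4779 and 2017, so part of the fall comes with fewer genes tested. With the level of Y-linked transcripts as a term 0 genes passed in resistant against mobocertinib, where the groups held 90.3% of the variance of that level and the design's SE was 2.74 times as large. Without a filter they were 11 in T-DM1 and 0 in resistant against mobocertinib, and the latter was also 0 by limma-voom and, by construction, without X and Y genes.

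Leaving out each library in turn gave 3182 to 5954 genes in mobocertinib, 2750 to 5784 in T-DM1, 3630 to 6136 in the combination and 4602 to 7349 in resistant nodules against vehicle, each lowest without vehicle 2. It gave 409 to 3222 for the difference of differences (lowest without vehicle 2, highest without vehicle 1), 0 to 1 in resistant against mobocertinib, 0 to 25 in T-DM1 against mobocertinib (highest without T-DM1 2) and 0 throughout in the combination against either drug.

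With an estimated correlation 0 lists were called in each comparison with vehicle, in the combination and resistant against mobocertinib and for the difference of differences, 2 in the combination against T-DM1 and 3 in T-DM1 against mobocertinib. With the offsets as well, 0 were called except 1 in the combination against mobocertinib, 1 in the combination against T-DM1 and 3 in T-DM1 against mobocertinib. The estimated correlations allow for genes of a list that move together between libraries. By fry 0 were called in the combination against mobocertinib, 1 in the combination against T-DM1, 0 in resistant against mobocertinib, 3 for the difference of differences and 7 in T-DM1 against mobocertinib. With the offsets 20 were called in resistant against mobocertinib, and with the term for the level of Y-linked transcripts also 20, none of them with an estimated correlation (adjusted p of at least 0.518).

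From TPM the direction turned for Ifi30 (0.50), Ccnd1 (1.91), Myc (0.31), Ager (0.74) and Cd274 (0.28) in mobocertinib against vehicle. In T-DM1 it turned for Birc5 (0.20), Rrm2 (1.05), Dusp6 (1.19), Etv5 (0.36), Ager (0.37) and Cd274 (0.71), and in the combination for Dusp5 (0.010), Cd274 (0.23), Myc (1.04), Mki67 (0.27), Top2a (0.093) and Ager (1.24). In resistant against vehicle it turned for Dusp6 (0.0065), Cd274 (0.064), Myc (1.12) and Mki67 (0.72). With the content covariate it turned for Ager (0.87) and Cd8a (−0.43) in mobocertinib, for Aldh1a1 (−0.027), Etv5 (0.28), Mki67 (−0.28), Top2a (−0.46) and Ager (0.64) in T-DM1, for Myc (0.17) and Ager (0.85) in the combination, and for Etv5 (0.15), Myc (0.56), Ager (0.14) and Cd8a (−1.96) in resistant nodules, all against vehicle.

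With the offsets the direction turned for Ndufa1 in mobocertinib (0.56), T-DM1 (0.68) and the difference of differences (−0.38), for Mki67 in T-DM1 (−0.38), Ccnd1 in the combination (−0.093) and Myc in resistant nodules against vehicle (0.069). With the term for the level of Y-linked transcripts it turned in resistant against mobocertinib for Ccnb1 (−0.071), Dcn (−0.60), Themis (−1.68), Tcf7 (−0.065), Ccl22 (−1.22) and Top2a (−0.065). With single libraries left out it turned as follows. Ccnd1 was at −0.092 to 0.70 in the combination against vehicle, negative without vehicle 2. In resistant against vehicle, Ccnd1 was at −0.28 to 0.93, negative without resistant 3, Myc at −0.98 to 0.053, positive without vehicle 2 (0.037) or resistant 1, Mki67 at −0.77 to 0.16, positive without vehicle 2 (0.076) or resistant 3, and Top2a at −0.89 to 0.082, positive without vehicle 1 or resistant 3 (0.037). In resistant against mobocertinib, Erbb3 was at −0.89 to 0.20, positive without mobocertinib 2 (0.16), resistant 1 or resistant 2 (0.16), Etv5 at −0.92 to 0.59, negative without mobocertinib 1 (−0.18) or resistant 2, and Cd8a at −1.50 to 0.58, positive without mobocertinib 2 or resistant 3 (0.30). None of these passed with all libraries.

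Depth limits genes with few counts, which was not simulated. In simulated data with the spread of these libraries, 200 genes above 1 log2 CPM were changed. Of these, 10% of 2-fold and 58% of 4-fold changes were called in mobocertinib against vehicle. In the combination against mobocertinib 6% and 66% were. A gene not called may thus have changed by such a fold. In the real mobocertinib against vehicle fit 5905 genes passed, so its p threshold was less strict than the simulated one. In the combination against T-DM1 DESeq2 called 75 genes and edgeR 0.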

Other observations

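T-DM1 against mobocertinib, a comparison added after the data had been seen, sets the drugs side by side, with vehicle in the fit but not compared. Cell-cycle and ERK feedback genes were higher under T-DM1 in all 3 nodules than in all 3 mobocertinib nodules. Cdc20 rose by 2.66 ± 0.349 (adjusted p = 0.0242), from 2.65 ± 0.989 to 16.8 ± 1.73 CPM, Dusp6 by 2.06 ± 0.255 (adjusted p = 0.0242), from 38.5 ± 7.47 to 161 ± 19.3 CPM, and Dusp5 by 2.35 ± 0.301 (adjusted p = 0.0242). Atp7b, a copper transporter, changed by −2.49 ± 0.341 (adjusted p = 0.028). The neutrophil chemokine gene Cxcl3 rose by 7.99 ± 1.14 (adjusted p = 0.0361) and was outside the rule for named genes and chosen after its values were seen. Cxcl3 did not pass without a filter, by limma-voom, from TPM or with the content covariate, nor Atp7b against a 1.5-fold change. The genes above were the 5 that passed, and 0 passed in edgeR without mobocertinib 1, mobocertinib 3, T-DM1 1 or T-DM1 3, 3 without mobocertinib 2 and 25 without T-DM1 2, where 1714 had an unadjusted p under 0.05 with all libraries, DESeq2 called 428 and limma-voom 4. With these 2 groups alone in the fit 0 genes passed in edgeR, where 2087 had an unadjusted p under 0.05. Libraries did not overlap for 3400 genes, where chance gives 10%.

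In the same comparison the proliferation list had a median of 2.48, with 1 member higher over all genes and 21 of 22 adjusted over the list alone (camera adjusted p = 1.59e-41; adjusted p = 0.0485 with an estimated correlation). ERK output genes had a median of 1.77, with 2 higher over all genes and 12 of 19 adjusted over the list alone (camera adjusted p = 6.12e-25; adjusted p = 0.0132 with an estimated correlation). Over all genes, both lists had 0 members called without mobocertinib 1, mobocertinib 3, T-DM1 1 or T-DM1 3, and the ERK list 1 without mobocertinib 2. FOXO targets had a median of −0.63, with 7 of 15 lower adjusted over the list alone (camera adjusted p = 1.74e-10; adjusted p = 0.0132 with an estimated correlation), and Pdk4 at −2.13 (adjusted p = 0.157). The 7 became 1 without mobocertinib 3, 2 without T-DM1 1 or T-DM1 3 and 4 without T-DM1 2. Interferon-response genes had a median of 1.36 and 8 higher adjusted over the list alone (camera adjusted p = 1.1e-13; adjusted p = 0.133 with an estimated correlation), or 13 without mobocertinib 2 or T-DM1 2 and 5 without mobocertinib 3, T-DM1 1 or T-DM1 3. With these 2 groups alone in the fit 4 interferon-response genes were called over the list alone, with a median of 1.35. Dendritic cell (median 1.69, camera adjusted p = 7.34e-06), immune checkpoint (1.17, 1.04e-05) and MHC class II genes (1.21, 1.25e-05) had higher estimates too, as did T (1.29, 0.00312), B (1.64, 0.0103) and plasma cell genes (2.77, 0.00418). None of these 6 lists was called with an estimated correlation (adjusted p = 0.141 to 0.679). Without T-DM1 1 the T, B and plasma cell lists were not called, and without mobocertinib 1 the T and B cell lists were not. Squamous and basal cell genes had a median of 3.16 and 8 higher adjusted over the list alone (camera adjusted p = 1.74e-11; adjusted p = 0.131 with an estimated correlation), with the cornified envelope gene Sprr1a at 3.05 (adjusted p = 0.15), and 2 were called without mobocertinib 3 and 5 without T-DM1 3.

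Targets of YAP, a growth-promoting coactivator, were higher in T-DM1 than in vehicle nodules for 8 of 14 genes (8 when adjusted over the list alone; median 1.72, camera adjusted p = 0.00258; adjusted p = 0.915 with an estimated correlation). Camera called the list higher than vehicle in every other group too (adjusted p of at most 0.0143). The 8 included Crim1 at 3.46 ± 0.395 (adjusted p = 0.000228), Ptpn14, which restrains YAP, at 2.63 ± 0.371 (adjusted p = 0.000443) and Amotl1 at 1.66 ± 0.343 (adjusted p = 0.00367), and the length-corrected median was 1.19. Amotl1 did not pass after length correction or with the content covariate. Neutrophil markers were lower in mobocertinib than in vehicle nodules for 7 of 17 genes (9 when adjusted over the list alone; median −2.06, camera adjusted p = 0.0075; adjusted p = 0.77 with an estimated correlation). They included Hdc, the histamine-making enzyme, at −3.25 ± 0.536 (adjusted p = 0.001) and Trem1 at −2.84 ± 0.592 (adjusted p = 0.00363), and the length-corrected median was −0.39 (adjusted p = 0.0686). Without vehicle 2, mobocertinib 2 or mobocertinib 3, 4 were called, and Trem1 did not pass with the content covariate or from TPM.

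Single libraries differed within groups. Immunoglobulin genes took 5.12% of the total in T-DM1 1 and 4.21% in resistant 1, and mitochondrial genes 6.41% in resistant 2. Heart and skeletal muscle genes scored 3.65 in mobocertinib 3, 3.32 in T-DM1 1 and −2.51 in combination 2. Xist stood at 44.1 and the Y-linked sum at 6.99 CPM of the library total in T-DM1 1, at 21.3 and 18.0 in T-DM1 2 and at 2.59 and 48.9 in mobocertinib 2. The labels do not say whether a library holds RNA of more than 1 mouse.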
